A study of Homo sapiens with 4 samples.

How the data were processed

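The series holds 4 libraries of RNA from Huh7 cells: an input and an RBM39 immunoprecipitate from shControl cells, and the same from shRBM39 cells, with 1 library per group. Per the labels' protocols, the immunoprecipitation used a commercial RNA immunoprecipitation kit and an antibody against RBM39, and the hairpin was delivered on a plasmid. The deposited table holds raw counts per gene symbol, whole numbers that the authors did not normalize. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and the hg38 build were used, but their roles and order, the counting program, its strand setting and the annotation release are not given in the sources used here. All 4 columns matched a sample by name, and 0 columns of other samples were present.

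In the deposited counts, 71.4% to 75.6% of the counts from 3 to 6 were even, so the mates of a pair seem to have been counted singly. Counting intervals are then too narrow, and an alternative with the counts divided by 2 before the interval was added after the data were seen. Of the 56303 features, 13 have numbers in place of gene names that look like dates made by a spreadsheet; they hold 0.0205% to 0.0335% of the counts and are never named. Features that overlap in the genome can share reads, and without a known strand setting reads of antisense genes cannot be told apart. Of the 19210 compared features, 14632 carry a current RefSeq symbol and 893 were matched through an older symbol (80.8% together). Coordinates are those of RefSeq on GRCh38, the assembly that hg38 names. The older-symbol match paired MT-CO2 with a nuclear copy, and that match entered the text only in the medians by annotation, where MT-CO2 counts as a pseudogene.

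Features with at least 10 counts in at least 2 of the 4 libraries were kept. Library sizes were scaled by TMM (edgeR 4.0.16 in R 4.3.3), with factors of 1.03, 1.09, 0.979 and 0.904 for the shControl input, shControl IP, shRBM39 input and shRBM39 IP. The 3 RNAs RN7SK, RN7SL1 and RN7SL2 made up 6.74%, 0.203%, 4.31% and 0.369% of the counts of these libraries, and mitochondrial transcripts 2.96%, 0.254%, 2.12% and 0.316%. Log2 ratios were computed after adding 0.5 to each count. A feature was listed as higher or lower when its log2 ratio was at least 1 in size and its exact conditional (Clopper-Pearson) 95% interval excluded a ratio of 1. For the difference of the log2 ratios the interval came from the counting standard error. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and each group has 1 library. The comparisons were IP over input in each culture, their difference (shRBM39 minus shControl) and shRBM39 over shControl in the inputs.

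IP and input were also tested over both cultures with edgeR's quasi-likelihood test in an additive model of culture and fraction, with Benjamini-Hochberg adjusted p under 0.05; the model has 1 residual degree of freedom, and any true difference between the cultures counts as error. DESeq2 1.42.0 was the alternative test. Tested on simulated counts with known changes, the edgeR step recovered 70 of 100 features changed 2-fold and 94 of 100 changed 4-fold, with 14 false calls among 19210. That simulation gave all features the same spread and no difference between the cultures. Its rates therefore hold for a simpler setting than these data. The pairwise step, simulated with counting noise alone, recovered 87% of changes of 1.5 and 98% of changes of 2.5 on the log2 scale for IP over input in shControl cells, 90% and 97% in shRBM39 cells, 93% and 96% between inputs and 85% and 97% for the difference, with 111, 87, 120 and 185 false listings.

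Before the data were examined, 18 gene lists and the rule for named genes were fixed. The rule took RBM39 and RFX1, the 10 highest and 10 lowest features of each pairwise comparison among those with at least 200 summed counts, ranked by the bound of the interval nearer to 0, up to 4 members of each list by size of the log2 ratio, and the 10 features of each direction with the smallest p in the edgeR test. Genes that mark sex were left out. LAMA3, FOSL1, U2AF1, CENPE, MT-RNR1 and FETUB fall outside the rule and were named after their values were seen. The lists were RFX1 and integrin signalling, extracellular matrix integrin ligands, SR proteins and RBM39 partners, hnRNP proteins, long non-coding RNAs (drawn up as nuclear retained, but also holding RNAs known from the cytoplasm), small structured non-coding RNAs, mitochondrially encoded transcripts, cytosolic ribosomal proteins, replication-dependent histones, secreted liver proteins, serine, glycine, asparagine and one-carbon metabolism, stress and unfolded protein responses, mitosis and DNA replication, p53 targets, cholesterol synthesis, interferon-stimulated genes, immediate early genes and markers of other cell types. A list is described by its median and the percentile of that median among 10000 random lists of the same size matched on deciles of mean expression, which describes these libraries and is not a test. Families of genes recognised by their symbols were added after the data were seen. Alternatives covered the scaling (DESeq2 size factors, total counts), the filter, the count added, thinning to the smallest library, a 4-fold threshold, the test and the block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Splicing was not analysed here, and the values of some single genes are not reported here.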

Results

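RNA immunoprecipitation followed by sequencing was performed in Huh7 cells, an established human hepatocellular carcinoma line, with an antibody against RBM39, an RNA-binding splicing factor. The cells carried either a control short hairpin RNA (shControl) or a hairpin directed at RBM39 (shRBM39). From each of the 2 cultures there was 1 library of input RNA and 1 library of the immunoprecipitate (IP), 4 libraries in all. None of the 4 was an IP with a control antibody. A rise over input therefore cannot be told from recovery that does not depend on RBM39, and recovery below means the ratio of IP over input. The total count was 20858382 in the shControl input, 41387762 in the shControl IP, 22249581 in the shRBM39 input and 45812488 in the shRBM39 IP. Each group had 1 library, so the pairwise differences below have no replicate check: their intervals are 95% intervals of counting error only, and no p-value is given for them. Of 56303 features in the count table, 19210 had at least 10 counts in at least 2 of the libraries and were compared. Features are called higher or lower when they differed by at least 2-fold (1 on the log2 scale) and the counting interval excluded equality.

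The transcript targeted by the hairpin was examined first. RBM39 (chromosome 20, 35701347 to 35742260, hg38) had 8701 counts in the shControl input and 8053 in the shRBM39 input. After TMM scaling these were 403 and 370 CPM, a log2 ratio of -0.13 (-0.17 to -0.08), so the RBM39 transcript in the input labelled shRBM39 was 0.917 times that of shControl. The knockdown named by the label was thus barely visible in the input RNA, and directions below refer to the libraries labelled shRBM39. RBM39 mRNA was itself more abundant in the RBM39 IP than in the input of both cultures. It had 46798 counts in the shControl IP and 91929 in the shRBM39 IP, which was 2.57 times its input level in shControl cells (log2 1.36, 1.33 to 1.39) and 5.999 times in the shRBM39 cells (log2 2.58, 2.55 to 2.62). The ratio was higher in the library labelled shRBM39, with a difference of 1.23 (1.18 to 1.27) on the log2 scale.

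RFX1, the transcription factor gene named in the series title (chromosome 19, 13961530 to 14006816), was a low transcript with 70 and 55 counts in the shControl and shRBM39 inputs and 319 and 317 counts in the IPs. It was 2.16 times higher in the IP than in the input of shControl cells (log2 1.11, 0.74 to 1.51) and 3.01 times higher in shRBM39 cells (log2 1.59, 1.18 to 2.04). The difference between the cultures, 0.48 (-0.08 to 1.03), and the difference between the inputs, -0.36 (-0.90 to 0.17), were not detectable at this depth. Counts per gene carry no information on exon use, so the splicing of RFX1 was not analysed here.

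**Figure D1:**
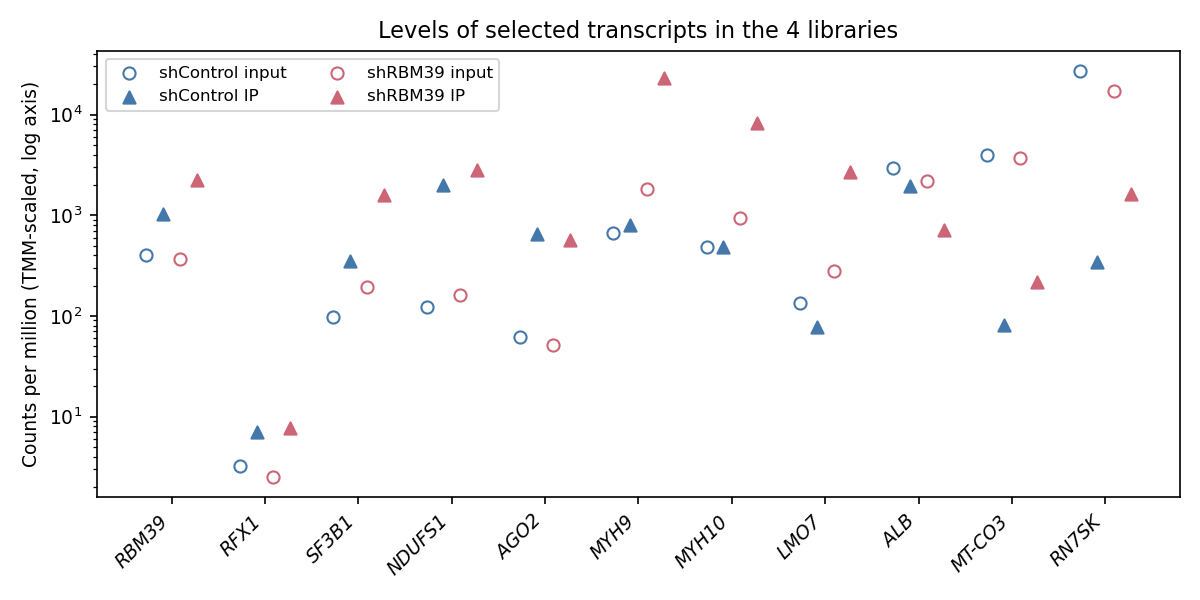
Level of 11 selected transcripts (x axis) in each of the 4 libraries, in TMM-scaled CPM on a log axis (y axis). Open circles are inputs, filled triangles are IPs, blue is shControl and red is shRBM39, each point being 1 library without an error bar. RBM39 lies near 403 and 370 in the inputs and at 1035 and 2219 in the IPs, while MYH9 reaches 23159 in the shRBM39 IP.

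The next comparison asked which RNAs were more abundant in the RBM39 IP than in the starting RNA of shControl cells. Ranked by the bound of the counting interval nearer to 0, the first features were NDUFS1, a subunit of respiratory complex I, at 16.4 times its input level (log2 4.03, 3.98 to 4.09), and CEP152, a centrosomal protein, at 14.2 times (log2 3.83, 3.72 to 3.94). AGO2, the Argonaute protein of RNA interference, was 10.5 times higher in the IP (log2 3.40), SMARCC2, a subunit of the SWI/SNF chromatin remodelling complex, 10.4 times (log2 3.37) and the kinase LMTK2 8.71 times (log2 3.12). At the other end, RN7SK, the RNA of the 7SK ribonucleoprotein, was 78.8 times lower in the IP than in the input (log2 -6.30, -6.32 to -6.28), and the mitochondrial MT-CO3 was 49.1 times lower (log2 -5.62, -5.67 to -5.57). In all, 1479 features were higher in the IP and 2173 were lower. With libraries scaled to total counts there were 1876 and 1862.

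Among the first 10 by that ranking were also ASB2 (log2 4.47, 3.71 to 5.49) and RGMA (log2 4.06, 3.64 to 4.56), with larger ratios and wider intervals than NDUFS1. PCDH20 and the clone-named feature RP11-310K10.1 both stood at log2 3.72 with near-identical counts, and GCSHP3, a pseudogene inside NDUFS1, stood at 3.50, so these features may share reads with their neighbours and are uncertain. The lowest 10 also held RPPH1, the RNA of RNase P (log2 -5.90), MT-ATP6 (-5.30), MT-ND2 (-5.26), MT-CO2 (-5.18) and MT-CO1 (-5.12). The remaining features of the lowest 10 were CTD-2651B20.6 (-7.65), RN7SKP203 (-6.23) and MTATP6P1 (-5.54). RN7SKP203 and MTATP6P1 are copies of RN7SK and of a mitochondrial gene, whose reads the counting could split.

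Of the fixed gene lists, the 15 mitochondrially encoded transcripts had the lowest median log2 ratio, -4.69, with the 13 mRNAs lower in the IP and the ribosomal RNAs MT-RNR1 (0.17) and MT-RNR2 (0.73) not, and the 21 measured small structured RNAs had a median of -2.97, with 20 lower. The list of long non-coding RNAs mixes nuclear ones such as MALAT1 and NEAT1 with cytoplasmic ones such as NORAD and GAS5. Its 19 measured members had a median of -0.98 with 9 lower, among them OIP5-AS1 (-2.01), HULC (-1.54), SNHG5 (-1.39) and KCNQ1OT1 (-1.25). All 3 medians lay below those of 10000 random lists matched on expression. Of the coding lists, serine, glycine, asparagine and one-carbon metabolism had the highest median, 0.72 (percentile 99.99), with 6 of 23 members higher, among them PHGDH (1.49) and ASL (1.24), and 2 lower, MTHFD2L (-1.86) and SLC7A11 (-1.52). Immediate early genes had a median of 0.48 (percentile 99.3) with 6 of 22 higher, including JUND (1.99) and IER2 (1.19).

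Splicing factor mRNAs stood less far apart. The 30 SR proteins and RBM39 partners had a median of 0.37 (percentile 95.9). Of these 4 were higher, namely SF3B1 (1.84), RBM39, SRSF6 (1.12) and U2AF2 (1.08), and U2AF1 (-1.07) was lower. The U2AF1 value is the one that equal raw counts in the IP and the input give, and the same held between the inputs. Equal raw counts are likely only at low depth, so U2AF1 is uncertain. The 25 hnRNP proteins had a median of 0.37 (percentile 92.9) with HNRNPL higher (1.21) and PTBP2 lower (-1.20). The 32 measured members of the RFX1 and integrin signalling list had a median of 0.24 (percentile 86.7), with 4 higher, including BCAR1 (1.35) and RFX1, and 3 lower, including the integrin subunits ITGB1 (-1.47) and ITGA1 (-1.20). The 22 extracellular matrix ligands of integrins had a median of -0.45 (percentile 0.52), with LAMB1 (-1.34) and LAMA3 (-1.18) lower and LAMA5 (1.01) higher. Of 37 mitosis and replication genes (median 0.30), 7 were higher, including KIF20A (1.59), MCM4 (1.46) and MCM7 (1.39), and CENPE (-1.05) was lower. Secreted liver proteins had a median of -0.31 (percentile 0.31), with APOB (-1.46) and CP (-1.03) as the lower members, and ribosomal proteins had a median of -0.15 (percentile 0.11), with 7 of 75 lower, including RPLP1 (-1.72) and RPS12 (-1.56). Stress and unfolded protein response genes had a median of -0.05 (percentile 17.4; 0.03 with total counts), with TRIB3 (1.26) and SESN2 (1.24) among 3 higher and HSP90B1 (-1.38) lower, and cholesterol synthesis genes one of 0.21 (percentile 71.8), with 3 higher, including MVD (1.54), and 2 lower, MSMO1 (-1.16) and SC5D (-1.12).

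In the shRBM39 cells the same comparison was led by overlapping genes. NDUFS1 was 17.4 times higher in the IP than in the input (log2 4.12, 4.07 to 4.17), CEP152 23.1 times (log2 4.53, 4.44 to 4.62), SMARCC2 12.5 times (log2 3.65), AGO2 11.1 times (log2 3.47) and LMTK2 9.59 times (log2 3.26), and these 5 were among the highest 10 in both cultures. The highest 10 also held MYH9, the heavy chain of non-muscle myosin IIA, at 12.7 times (log2 3.66, 3.65 to 3.68), and LMO7, an actin-associated LIM domain protein, at 9.64 times (log2 3.27, 3.23 to 3.31). The lowest 10 held MT-CO3 (log2 -4.09, -4.13 to -4.06) and other mitochondrial and small RNAs, of which 6 features were shared with the lowest 10 of shControl cells. Here 1016 features were higher in the IP and 1729 lower.

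The clone-named features RP11-485O10.2 (4.55), RP11-485O10.3 (3.72) and AC007383.4 (3.39) completed the highest 10, and their reads cannot be assigned with certainty. The lowest 10 held RN7SKP255 (-4.24), RN7SKP203 (-4.34), RN7SL4P (-3.79), RN7SL2 (-3.48), RPPH1 (-3.50), MT-ATP6 (-3.87), MT-CO2 (-3.72), MTCO3P12 (-4.21) and MTATP6P1 (-3.63), most of which have near-identical copies. Of the features higher in the IP, 436 were higher in both cultures, where independent lists would share 78.2, and 979 were lower in both, where independent lists would share 196. The split of higher and lower features depended on scaling, being 718 and 2164 when libraries were scaled to total counts.

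Mitochondrial transcripts had a median of -3.16, with 13 of 15 lower, small structured RNAs a median of -1.61, with 13 of 21 lower, and long non-coding RNAs a median of -0.66, with 4 of 19 lower, including OIP5-AS1 (-1.56) and NEAT1 (-1.03). Secreted liver proteins were lower in this IP, with a median of -0.996 below all random lists and 16 of 32 members lower, including APOB (-1.85), CP (-1.68), ALB (-1.62) and C5 (-1.58). Extracellular matrix ligands had a median of -1.02, below all random lists, with 12 of 22 lower, among them FGG (-1.39), LAMB1 (-1.36) and COL1A2 (-1.34). The fibrinogen genes and VTN stand in both lists. SR proteins and partners had a median of 0.53 (percentile 99.96) with SF3B1 (3.03) and RBM39 higher, hnRNP proteins a median of 0.48 (percentile 99.6) with 0 members past 2-fold, and mitosis genes a median of 0.42 (percentile 99.6) with KIF20A (1.12), CDT1 (1.10) and MCM7 (1.05) higher.

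Integrin signalling genes had a median of 0.30 (percentile 96.9) in the shRBM39 cells, with 5 higher, including ACTN4 (1.66) and RFX1, and 5 lower, including ITGB1 (-1.73) and ITGA2 (-1.64). Serine and one-carbon genes had a median of 0.49 (percentile 99.8) with CBS higher (1.15) and MTHFD2L (-1.96) and SLC7A11 (-1.46) lower, and immediate early genes a median of 0.55 (percentile 99.97) with JUND (2.08), NR4A1 (1.11) and KLF2 (1.08) higher and CYR61 (-1.41) lower. The stress and unfolded protein response list had a median of -0.21 (percentile 1.84), with the chaperones HSP90B1 (-1.71), HSPA5 (-1.30) and DNAJC3 (-1.13) lower. Cholesterol synthesis genes had a median of -0.19 (percentile 2.06), with MSMO1 (-1.17) among the lower members. Ribosomal protein mRNAs, with 4 of 75 lower, had a median of 0.01 that turned to -0.11 when scaled to total counts.

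**Figure D2:**
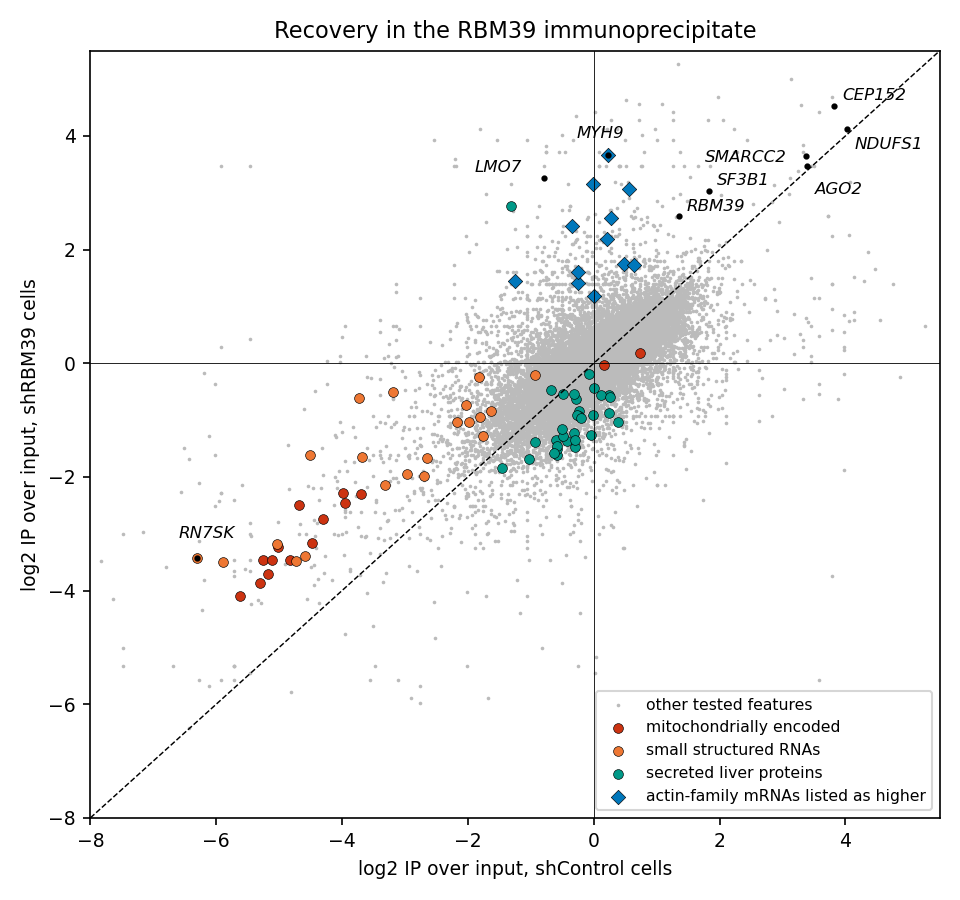
Log2 ratio of IP over input in shControl cells (x axis) against that in shRBM39 cells (y axis), each point being 1 of the 19210 compared features, with 1 feature outside the axes; the dashed line marks equal recovery. Small structured RNAs and 13 of 15 mitochondrial transcripts (not the ribosomal RNAs MT-RNR1 and MT-RNR2) lie at the lower left and above the line. Most secreted liver proteins lie below it. The 12 actin-family mRNAs listed as higher, a grouping chosen after the values were seen, lie well above it. They encode actin-associated proteins and not actins. The secreted protein gene at the upper left, FETUB, had 0 counts in the shRBM39 input and 12 or fewer in the other libraries.

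The contrast between the cultures asked which RNAs were recovered more or less with the RBM39 antibody in the cells labelled shRBM39. Among the 10 highest features by the same ranking, 6 encode actin-associated proteins, which were not a list fixed beforehand. The difference of log2 ratios was 4.07 for LMO7 (3.99 to 4.15), 3.43 for MYH9 (3.40 to 3.46), 3.22 for LIMCH1, an actomyosin-associated protein (2.92 to 3.51), 3.16 for MYH10, the heavy chain of non-muscle myosin IIB (3.12 to 3.20), 2.76 for TMOD3, which caps actin filament ends (2.67 to 2.84), and 2.51 for MYH14, the heavy chain of non-muscle myosin IIC (2.44 to 2.58). In shControl cells these mRNAs were not called higher in the IP, with MYH9 at 0.23, MYH10 at -0.01, LMO7 at -0.80 and LIMCH1 at -0.51. RN7SK (2.88, 2.85 to 2.90) and RMRP, the RNA of RNase MRP (2.69, 2.52 to 2.85), were also among the highest. Both were less depleted in the shRBM39 IP relative to its input, and part of this came from lower inputs. Log2 shRBM39 over shControl in input was -0.65 for RN7SK and -1.41 for RMRP. RMRP stood at 129 CPM in the shControl input and 48.7 in the shRBM39 input, and at 14.1 and 34.3 in the IPs.

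At the other end were ASB2 (-2.81, -3.79 to -1.83), RGMA (-1.81, -2.39 to -1.24), MOXD1 (-2.09), FOLH1 (-1.89), NYNRIN (-2.06), SLC25A29 (-2.23) and DLK1 (-2.42, -3.61 to -1.23). DLK1 had 18 and 8 counts in the shRBM39 libraries. In the shControl input ASB2 and SLC25A29 had 12 counts each, MOXD1 24, NYNRIN 26, FOLH1 36 and RGMA 42. LARS2, the mitochondrial leucyl-tRNA synthetase (-1.40, -1.61 to -1.19), and RBX1, a subunit of cullin ubiquitin ligases (-1.35, -1.55 to -1.15), rested on deeper counts. A lower ratio can also come from a higher input. Log2 shRBM39 over shControl in input was 2.19 for FOLH1, 1.63 for MOXD1, 1.41 for SLC25A29 and 1.27 for ASB2. It was 0.95 for LARS2, 0.79 for RBX1, 0.59 for RGMA, 0.37 for NYNRIN and -3.78 for DLK1. FOLH1 stood at 2.39 CPM in the shControl IP and 2.94 in the shRBM39 IP. The clone-named features RP11-56B16.4 (2.90), RP11-29G8.3 (2.61) and RP11-304L19.8 (-2.35) met the same rule and are uncertain, as is MYH10 in part, because it overlaps NDEL1 in the annotation. In all, 843 features were higher and 526 lower in this contrast, a split that turned to 570 and 887 with libraries scaled to total counts.

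Mitochondrial mRNAs were less depleted in the shRBM39 IP: the list had a median difference of 1.49 with the 13 mRNAs higher, including MT-ND6 (2.19), MT-ND2 (1.79) and MT-ND1 (1.77), while MT-RNR1 (-0.21) and MT-RNR2 (-0.56) were not. Small structured RNAs had a median difference of 1.19 with 12 of 21 higher, including RNU4-1 (2.90) and RPPH1 (2.40). Both medians lay above all random lists. The small structured RNAs also had a median of -0.55 for shRBM39 over shControl in input, which adds to their difference. Long non-coding RNAs had a median difference of 0.23 (percentile 98.97) with 2 of 19 higher, including SNHG5 at 1.01, and MALAT1 at 0.51. Secreted liver proteins had a median difference of -0.76, below all random lists, with 6 of 32 lower, including A1BG (-1.42), ITIH3 (-1.22), AFP (-1.17) and APOE (-1.12). Extracellular matrix ligands had a median of -0.45, below all random lists, with COL1A2 at -0.97 and FGB at -0.92; its only member past 2-fold, LAMA3, was higher (2.08, 0.96 to 3.20) on 16 to 58 counts per library. Cholesterol synthesis genes had a median of -0.31 (percentile 0.06) with ACAT2 (-1.09) among the lower members, stress response genes a median of -0.23 (percentile 0.84), with HSPA5 at -0.83, and serine and one-carbon genes a median of -0.23 (percentile 0.75) with 0 members past 2-fold.

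Of the splicing list, RBM39, SF3B1 (1.20, 1.12 to 1.28) and CLK4 (1.10, 0.82 to 1.38) were higher, while the list's median of 0.06 lay within the random range (percentile 87.4) and turned to -0.13 with total counts. The integrin signalling list had a median of -0.03 (percentile 45.97) and 0 members past 2-fold in either direction, with values of 0.99 for ACTN1, -0.87 for ITGB8 and 0.79 for ACTN4. Log2 shRBM39 over shControl in input was 2.78 for ITGB8, 1.54 for ACTN4 and 0.52 for ACTN1. Ribosomal proteins had a median of 0.17, above all random lists, which turned to -0.019 with total counts. The hnRNP list had a median of 0.05 (percentile 80.5), which turned to -0.15 with total counts, and mitosis genes one of 0.09 (percentile 95.2), with ANLN at 0.96 and CENPF at 0.82; this median turned to -0.11 with total counts. Immediate early genes had a median of -0.03 (percentile 45.5), with FOSL1 lower (-1.24, -2.39 to -0.09) on 12 to 90 counts per library and CYR61 at -0.92. Scaling to total counts shifted all features by -0.19 in this contrast, by 0.08 in shControl and by -0.11 in shRBM39 cells, and by -0.08 between the inputs.

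The inputs were compared for differences in the starting RNA. The input labelled shRBM39 held 4.62 times as much VIM, the mesenchymal intermediate filament vimentin (log2 2.21, 2.08 to 2.34), 6.39 times as much SAA1, an acute-phase protein (log2 2.68, 2.29 to 3.11), and 8.78 times as much CCDC80 (log2 3.13, 2.69 to 3.64). It held 13.8 times less DLK1 (log2 -3.78, -4.60 to -3.13), 6.03 times less S100A9, a calcium-binding protein (log2 -2.59, -2.73 to -2.46), and less of the apolipoprotein APOA2 (log2 -1.96, -2.02 to -1.91). In all, 979 features were higher and 1102 lower in the shRBM39 input. With total counts there were 768 and 1304.

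The other features of the highest 10 were MALRD1 (2.94), SAA2-SAA4 (2.83), BCAS1 (2.56), SLPI (2.49), COL12A1 (2.46), HDAC9 (2.43) and RP11-124N14.3 (2.27). Those of the lowest 10 were FUT3 (-3.67), LINC00540 (-2.43), HPN (-2.42), RARRES2 (-2.41), HTRA3 (-2.34), LAMA4 (-2.18) and PLXND1 (-1.85). The IPs, which share no library with the inputs, differed the same way for 1738 of these 2081 features (83.5%), and 924 of them did so by at least 2-fold. The Spearman correlation of both differences across all compared features was 0.54, and genes are not independent replicates.

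Mitosis and replication genes had the highest median in this comparison, 0.64, above all random lists, with 34 of 37 members above 0 and 8 past 2-fold, including MCM7 (1.73), MCM6 (1.66), MCM3 (1.48) and RRM1 (1.42). hnRNP proteins had a median of 0.51 (percentile 99.8) with HNRNPM (1.38), HNRNPU (1.22), HNRNPH2 (1.06) and HNRNPH1 (1.01) higher, and SR proteins and partners a median of 0.41 (percentile 99.5) with 0 members past 2-fold. Of the integrin signalling list (median 0.14, percentile 79.3), 7 of 32 were higher and 0 lower, including TLN1 (1.64), TLN2 (1.56), ACTN4 (1.54) and FLNA (1.24). Ribosomal proteins had a median of -0.30, below all random lists, long non-coding RNAs one of -0.40 (percentile 0.08) and small structured RNAs one of -0.55 (percentile 0.03), with RMRP at -1.41. Secreted liver proteins went both ways (median -0.09, percentile 2.03), with HP at 1.10 and APOA2 at -1.96. Mitochondrial transcripts had a median of -0.11 (percentile 2.07), and cholesterol synthesis genes one of -0.20 (percentile 0.25) with 0 members past 2-fold. Stress response genes had a median of -0.18 (percentile 0.93), extracellular matrix ligands one of -0.24 (percentile 0.77), with 3 higher and 1 lower, serine and one-carbon genes one of 0.15 (percentile 69.1), with MTHFD1 (1.09), GLDC (1.07) and PHGDH (1.03) higher and ALDH1L2 (-1.04) lower, and immediate early genes one of 0.00 (percentile 55.1), with CYR61 at 1.27.

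Replication-dependent histones (18 measured) had medians of 0.37, 0.31, -0.18 and 0.17 in the shControl IP, the shRBM39 IP, the contrast and the inputs, p53 targets (18 measured) of -0.05, -0.19, -0.19 and -0.18, and interferon-stimulated genes (21 measured) of 0.18, 0.18, -0.15 and 0.07. All of these lay within the random range, and with total counts the p53 median in shControl turned to 0.03 and the interferon median between inputs to -0.01. Of 24 markers of fibroblasts, endothelium and blood, 9 were measured, and their median between the inputs was -0.13 (percentile 40.0), with LYZ at -0.54 and PECAM1 at 0.51. Between the IPs and inputs their medians were -0.21, -0.24 and, for the contrast, -0.11.

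**Figure D3:**
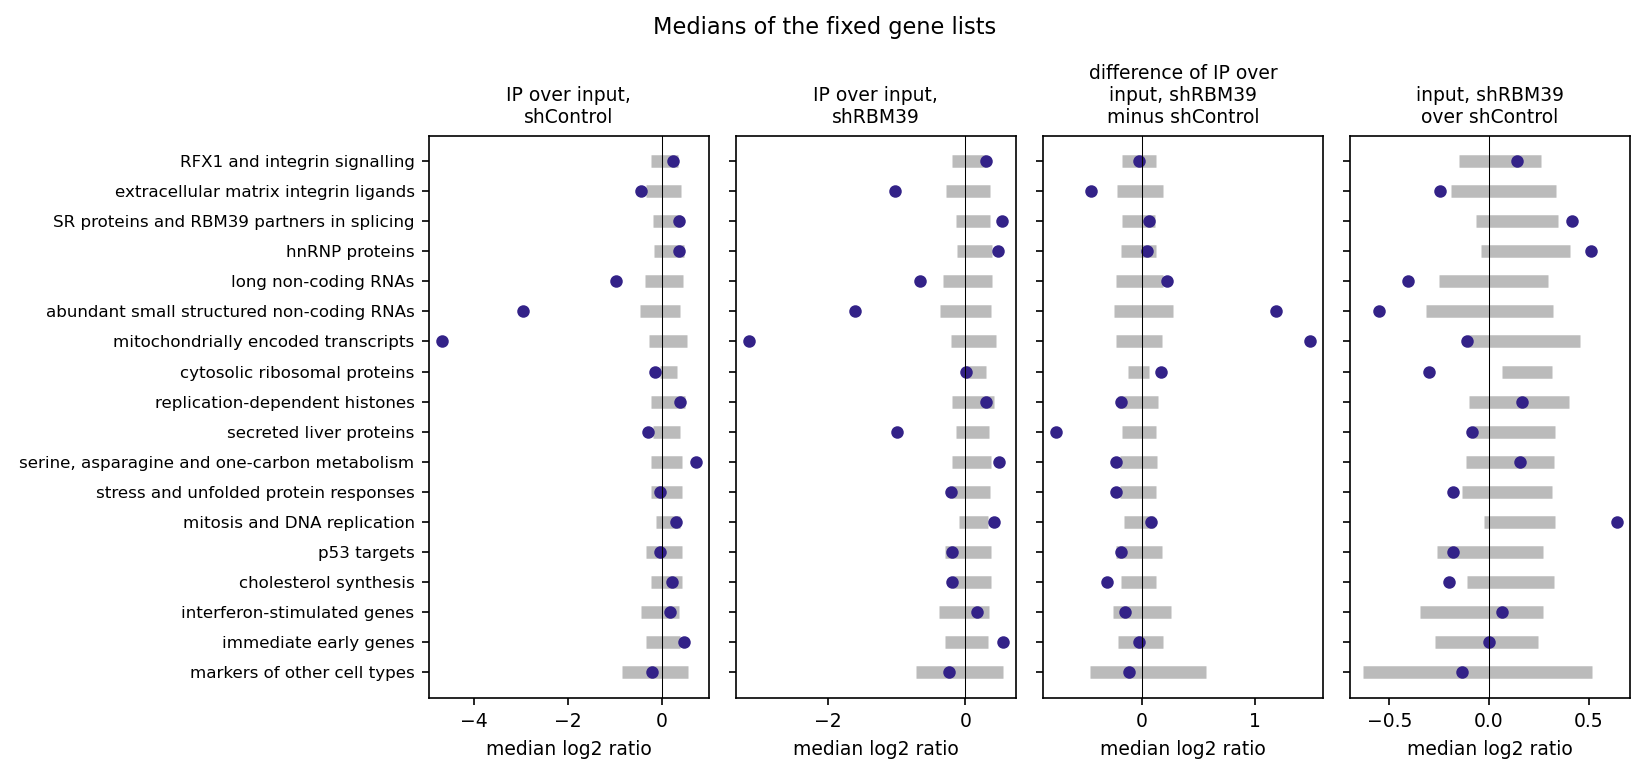
Median log2 ratio (x axis) of each of the 18 fixed gene lists (rows) in the 4 comparisons (panels, each with its own scale). Dots are the medians and grey bars span the central 95% of 10000 expression-matched random lists. The mitochondrial list lies at -4.69 in the shControl and -3.16 in the shRBM39 IP, and the mitosis list lies at 0.64 between the inputs.

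The comparison of IP and input over both cultures was the only test with replication, each culture giving 1 pair. Recovery of NDUFS1, CEP152, AGO2, SMARCC2 and LMTK2 rose in the IP, together with that of NR3C2, the mineralocorticoid receptor. For NDUFS1 the log2 ratio was 4.08 with SE 0.24 and adjusted p 4.177e-10, and for AGO2 it was 3.44 with SE 0.20 and adjusted p 2.788e-10, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in 2 of 2 cultures each. By the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, RBM39 (1.97, SE 0.26, adjusted p 1.197e-05) and RFX1 (1.35, SE 0.23, adjusted p 0.000169) also rose in the IP, in 2 of 2 cultures. The test called 3698 features higher and 3381 lower in the IP of 19210 tested. With total counts it called 2850 higher and 3009 lower, so which direction held more features depended on the scaling.

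The 10 smallest p-values among features that rose belonged, besides these, to AC007383.4 (3.32), GCSHP3 (3.49), RP11-485O10.2 (3.95) and RP11-485O10.3 (3.06), with NR3C2 at 2.67. Among features that fell they belonged to RN7SL4P (-4.08), RN7SKP255 (-4.76), MTCO1P12 (-4.05), MT-ATP8 (-4.13), RN7SL5P (-4.01), MTCO3P12 (-4.72), MT-TT (-3.29), RN7SKP203 (-5.19), Metazoa_SRP (-4.22) and MTATP6P1 (-4.54), which are mitochondrial or 7SK and 7SL RNAs and their copies. Without the culture as a block, edgeR called 0 features in either direction, with 4143 at an unadjusted p under 0.05, and DESeq2 with the block called 2598 higher and 2097 lower. The model has 1 residual degree of freedom, which holds the difference in recovery between the shControl and shRBM39 cultures. Each SE is the size of the log2 ratio divided by the square root of the test's F statistic. The p-values and SEs rest largely on a spread borrowed across genes, which carried 19.2 prior degrees of freedom. The IP and input of a culture do not replicate each other, and labels do not say how the cultures were made. The p-values and SEs thus describe these 4 libraries alone and do not measure the spread between replicate cultures of one label.

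Within the fixed lists, the same test gave 13 mitochondrial transcripts that fell and 0 that rose (13 and 0 adjusted over the list alone), 20 small structured RNAs that fell (21 adjusted over the list alone) and 15 long non-coding RNAs that fell (17 adjusted over the list alone). Of secreted liver proteins 20 fell and 0 rose (23 and 0 adjusted over the list alone), and of extracellular matrix ligands 11 fell and 1 rose (12 and 1 adjusted over the list alone). Of serine and one-carbon genes 16 rose and 2 fell (16 and 2 adjusted over the list alone), of mitosis genes 16 rose and 1 fell (18 and 2 adjusted over the list alone), and of the integrin signalling list 14 rose and 6 fell (14 and 6 adjusted over the list alone). Of SR proteins and partners 13 rose and 1 fell (15 and 2 adjusted over the list alone), of hnRNP proteins 10 rose and 1 fell (11 and 1 adjusted over the list alone), and of immediate early genes 10 rose and 2 fell (12 and 2 adjusted over the list alone). Ribosomal proteins gave 1 that rose and 11 that fell (1 and 9 adjusted over the list alone), cholesterol genes 7 and 7 (7 and 7 adjusted over the list alone), stress response genes 5 and 8 (6 and 9 adjusted over the list alone), histones 5 and 0 (3 and 0 adjusted over the list alone), interferon genes 7 and 0 (7 and 0 adjusted over the list alone), p53 targets 3 and 2 (3 and 2 adjusted over the list alone) and other-cell markers 0 and 3 (0 and 3 adjusted over the list alone).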

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

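The tests of explanations in this part were all chosen after the results they concern had been seen. With 1 library per group, a difference between the cultures cannot be separated from a difference between single preparations.

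In 23 features the IP was lower than the input in shControl cells and higher in shRBM39 cells, and in 7 features the reverse held; they are listed because the cultures moved in opposite directions, and the difference was not tested. Most rest on few counts: PCDH15 had 14, 0, 0 and 10 counts in the shControl input, shControl IP, shRBM39 input and shRBM39 IP, and CD274 had 0, 14, 10 and 1. TMOD2, with 156, 138, 58 and 304 counts, was the deepest of the 30 in the shRBM39 IP; it was picked out after its values were seen, and the strand and overlap of its reads are unknown.

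RBM39 mRNA was recovered more in the IP labelled shRBM39, where less RBM39 protein was meant to be present. An exchange of the IP libraries between the cultures would make features that differ between the inputs differ the opposite way between the IPs, but 83.5% of them (Wilson interval 81.9% to 85.0%) differed the same way, which argues against it. An exchange of both libraries of each culture stays open, since RBM39 differed between the inputs by -0.13 on the log2 scale and there are no replicate cultures to give that value a spread. The knockdown itself, with a difference in recovery of 1.23, also cannot be told apart from a difference between 2 single cultures. No protein measurement was analysed here.

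The 13 mitochondrial mRNAs and 20 of 21 small structured RNAs were lower in the shControl IP, 13 of each in the shRBM39 IP, and in the contrast 13 and 12 of them were called higher. The median difference of the mitochondrial list was at least 1.29 under the 3 scalings. The alternatives shift all features alike, by -0.0045 with DESeq2 size factors and -0.19 with total counts. They could not have brought the median to 0, so this result does not weigh scaling as a cause. The place of the list above all random lists is one that a scaling cannot alter. Input-like RNA carried over into that IP may be part of the pattern: the share it needs was 7.04% by the median of 13 mitochondrial transcripts and 22.4% by that of 20 small RNAs, a 3.19-fold gap. A uniform carry-over was to be rejected at a gap over 2-fold. The bootstrap interval, added after the gap was seen, ran from 1.35 to 5.29, which left it open by that rule. That bootstrap draws members and takes their differences as noise, while a uniform carry-over needs the same share in each. The quartiles of the shares were 5.74% and 12.4% for the mitochondrial transcripts and 10.8% and 34.5% for the small RNAs. These argue against 1 uniform share as the whole cause, and carry-over as a part of it stays open. The knockdown, with a median difference of 1.49, cannot be told apart from a difference between single preparations.

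Higher recovery in the IP labelled shRBM39 was seen for 12 of 77 mRNAs from families of actin-associated proteins. These are called actin families here and hold no actin gene. The pattern is a hypothesis found and tested on the same data: the families were drawn up after MYH9, MYH10, MYH14 and TMOD3 had been seen. Of the other 73 members 8 were higher in the contrast. Random lists matched on gene span and expression held up to 4 at the upper end of their central 95% and 8 at most. The other members were also grouped after the data were seen, and the random lists were not chosen that way. The comparison therefore cannot decide whether span and level are the cause. Carried-over input RNA moves a log2 ratio toward 0 and not past it. The counting intervals of 12 of the 12 listed members lay above both 0 and the shControl ratio in the shRBM39 cells, which carry-over alone would not give. Picking members by the contrast places them above the shControl ratio. It also places most of them above 0, since their median shControl ratio was 0.10, with TMOD2 lowest at -1.24. The position of the listed members is thus not a separate test of carry-over. Their median in the shRBM39 cells, 1.9604, is no separate evidence for the same reason. Over all 77 members the medians were 0.51 in shRBM39 and 0.39 in shControl cells. The knockdown stays open with a median difference of 2.13, as does a difference between single IPs, such as co-purified actomyosin complexes, for which no test was run.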

How the results depend on the processing

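The halved counts and the total counts for gene families were the alternatives chosen after the data were seen. Counts of higher and lower features moved by over 1.5 times as follows, in the order shControl, shRBM39, contrast, inputs where several are given. At a 4-fold threshold there were 138, 188, 308 and 197 higher and 515, 365, 131 and 293 lower, which a stricter threshold brings by construction. With at least 10 counts in all 4 libraries the higher features were 644 in shRBM39 cells and 460 in the contrast and the lower ones 636 between inputs, from fewer features tested; with no filter 1624 were higher in shRBM39 cells. With 5 added to each count the contrast held 517 higher and 263 lower. With halved counts it held 451 and 237, and the inputs 687 lower. With total counts the contrast held 887 lower, and RBM39 stood at 1.44 in shControl cells, 2.47 in shRBM39 cells, 1.03 in the contrast and -0.20 between inputs, all in the direction given. Over both cultures, edgeR without the block called 0 higher and 0 lower (4143 at an unadjusted p under 0.05), and DESeq2 called 2097 lower, with 2980 adjusted p-values missing. The ribosomal protein median in the contrast reversed to -0.019 with total counts. Except where the construction shows it, the cause was not tested. The other 73 values of main results stayed within 1.5 times or within their interval, but 8 of them, the numbers of lists outside the random range under other scalings, could not have moved. Without a filter edgeR called 4628 higher and 2797 lower. Of values for single genes and lists, 933 kept their call or stayed within their range, 15 list medians moved, all with total counts, 7 medians within the random range changed sign with total counts and 1 with at least 10 counts in all 4 libraries, and 8 gene values fell short of the 4-fold threshold. With 1 library per group, no replicate could be left out. Depth limits RFX1, with 55 to 70 counts in the inputs.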

Other observations

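The gene families compared in this part and their values with total counts were all chosen after the data had been seen. Within the actin families, the spectrins SPTBN1 (1.98) and SPTAN1 (1.85) and the tropomodulins TMOD1 (2.29) and TMOD2 (2.70) were higher in the contrast of recovery between the cultures, beside the myosin heavy chains of the report. The 3 alpha-actinins had a median of 0.84 (percentile 98.2) and were not past 2-fold, and the 9 Arp2/3 subunits (-0.10) and 6 coronins (-0.14) lay within the range of random lists. So did myosin light chains (-0.0037), tropomyosins (0.11), capping proteins (-0.13), PDZ and LIM domain proteins (0.06) and talins and vinculin (0.07). Medians above that range were those of tropomodulins (2.70), alpha-actinins (0.84), spectrins (0.57), filamins (0.53) and conventional (0.53) and unconventional (0.24) myosins. Of the other cytoskeletal families, 7 keratins had a median of -0.26, 16 tubulins one of -0.23 and 34 kinesins one of 0.11, all within the random range; the kinesin median turned to -0.09 with total counts. Over all 77 members of the actin families the median was 0.19 with TMM and -0.00078 with total counts (percentile 100, which a scaling cannot alter and which includes the 4 genes that prompted the grouping), and 12 members were higher with TMM and 10 with total counts.

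Solute carriers (257 measured) had a median difference of -0.17 between the cultures, below all random lists, while 185 TMEM genes had one of -0.07 (percentile 6.04). Proteasome subunits, which are not membrane proteins, had a median of -0.27, also below all random lists, and 428 zinc finger genes one of 0.07 (percentile 99.99), which turned to -0.12 with total counts.

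By annotation, snoRNAs (81 features) had a median log2 ratio of -1.36 in the shControl IP and -0.58 in the shRBM39 IP, pseudogenes (593) -0.45 and -0.12, and long non-coding RNAs (895) -0.28 and -0.22, while protein-coding genes (13570) stood at 0.07 and 0.06. The older-symbol match placed MT-CO2 among the pseudogenes.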
